A study of Mus musculus with 48 samples.

How the data were processed

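Mouse embryonic stem cells of the E14TG2a line, grown with LIF and the inhibitors PD0325901 and CHIR99021, expressed HA-tagged KDM4A, KDM4B, KDM6A or KDM6B, either full length or with the intrinsically disordered region deleted (ΔIDR). Every sample title carries OE, read here as overexpression, and no title names a loss of the cells' own enzyme. The 48 libraries form 24 groups of 2. They comprise 16 ATAC-seq libraries and 16 CUT&RUN libraries for the HA tag, each over all 4 demethylases, 8 CUT&RUN libraries for H3K9me3 (KDM4A and KDM4B) and 8 CUT&Tag libraries for H3K27me3 (KDM6A and KDM6B). The labels name no library without a tagged demethylase, so full length served as the reference. They give replicate numbers but do not say whether replicates were separate cultures, so the p-values measure only the spread between libraries, which may be technical.

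One peak list per library was used, on build GRCm39. Per the submitters' processing notes, fastp, BWA, SAMtools, Picard, MACS2 and featureCounts were used, with no versions, settings or roles given. The deposited ATAC lists have the MACS2 narrow format and the deposited histone lists the MACS2 broad format. In both, the deposited values are a fold enrichment of pileup over local background, a −log10 p-value, a −log10 q-value and a score of 10 times that last value (rounded down); the lowest −log10 q was 1.30 in ATAC lists and 1.00 in histone lists, which are q limits of 0.05 and 0.1. The deposited HA lists have no header and no stated caller. From their values, each HA peak carries a signal (peak height in reads or fragments, at least 6, not normalised by the authors), a local background, a Poisson p-value of that height against that background, an adjusted p-value and its −log10. That reading was checked on the files. The p-value was reproduced within a relative tolerance of 0.001 in 76.6 to 94.0% of a library's peaks (median 89.1%), and the background was a whole multiple of the library's lowest, within 0.01, in at least 99.8%. The share of p-values reproduced was lower in both ΔIDR than in both full-length libraries of every demethylase. In KDM4A it was 76.8 and 76.6% against 92.6 and 93.4%, so the reading is least sure in the KDM4A ΔIDR lists. Heights and folds are the authors' values, and in the comparisons fixed beforehand they only ranked peaks within a list. ATAC and histone peaks were ranked by fold, and HA peaks by −log10 of the adjusted p-value, with height deciding only between equal values. After the lists were seen, heights and folds were also compared between libraries: as counts of tall peaks, as heights at shared regions, and as heights, folds or recovered pileup relative to other regions of the same library. Heights not set against other regions carry any difference in depth.

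No read totals accompany the lists, so the depth behind each library is unknown and no counting interval is given. As an index of depth, a local background of each HA and ATAC list was used, called its lowest background below. For HA it is the lowest value in the list, and it ranged from 0.958 to 1.21. Since nearly all HA backgrounds are whole multiples of it, it may be a scaling unit, and whether it tracks read number is not known. For ATAC, pileup and background at each summit were recovered as the whole pileup that gives both the deposited fold and the deposited −log10 p (peaks with −log10 p up to 40). This returned a match for at least 99.9975% of such peaks per library. The most frequent recovered background, after rounding, was taken as the lowest, so the HA and ATAC indices are different statistics. It ranged from 0.412 to 1.10. On simulated peaks the recovery was right in 100.0% of 2809.

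Peaks on chromosomes 1 to 19, X and Y were kept. For HA and ATAC, the peaks of the 4 libraries of a comparison were merged where they overlapped by at least 1 bp, and a library held a region when 1 of its peaks overlapped it by at least 1 bp. For histone marks, fixed windows of 1 kb were used, and a library held a window when peaks covered at least 50% of it. Gained regions were in both ΔIDR and neither full-length library, lost regions the reverse, and shared regions in all 4. The 4 patterns that mix 1 library of each variant gave the number expected from library-to-library variation. The share of HA peaks in accessible chromatin or in the own mark (H3K9me3 for KDM4A and KDM4B, H3K27me3 for KDM6A and KDM6B) was taken against regions found in at least 2 of the same demethylase's 4 libraries. Coverage of HA regions by the own mark, and the share of HA regions with an ATAC peak, were taken per library.

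With 2 libraries against 2, the smallest two-sided exact p is 0.333, so single comparisons are given as mean, SD and whether the 4 libraries overlap. Over demethylases, a two-sided exact permutation test exchanged variant labels within each demethylase (6 arrangements each, 1296 in all, smallest p 0.00154); its value is the mean over demethylases of ΔIDR minus full length. One mark alone has 36 arrangements and a smallest p of 0.0556. Benjamini-Hochberg adjustment ran over the 18 planned tests, with 0.05 as the threshold. In simulated data this test gave an exact p under 0.05 in 4% of 500 draws with no effect. It did so in 42.6% with an effect of 1 library SD and in 100.0% with 3. The simulated effect had the same direction and size in all 4 demethylases. Effects of opposite direction cancel in the mean, so a high p does not exclude an effect in single demethylases. In a simulated HA comparison, 81.9% of 1000 planted gains and 78.2% of 500 planted losses were recovered (81% expected), and planted regions made up 83.2% and 68.5% of the calls. There, each library kept most of the regions. Of the real KDM4B HA regions, 28242 of 35508 were in 1 library only. The simulation therefore checks the counting and does not give the accuracy of the real calls.

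The groups, tests, definitions and the main alternatives were fixed before the data were examined. Alternatives fixed then were a stricter threshold (−log10 q of at least 5), equal numbers of peaks, another overlap rule, a looser definition of gain and loss, all sequences, accessible or marked regions of the same variant, replicate number as a block, and each library left out in turn. Alternatives without tall HA peaks (height above 50), at equal lowest ATAC background (pileup and background thinned to the lowest of a demethylase's 4 libraries, which equals depth only as far as that index does), without chromosomes 6 and 8, and without KDM4B were added after the lists were seen. So were 8 further tests, adjusted among themselves, and the common sets used to class HA regions: accessible in at least 12 of 16 ATAC libraries (27.0 Mb), H3K27me3 in at least 6 of 8 libraries (45.5 Mb) and H3K9me3 in at least 6 of 8 (14.7 Mb).

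The rule for named regions, fixed beforehand, takes the gained and the lost region of highest rank per comparison, by the lower of the 2 libraries' ranks. Ranks were by deposited fold for ATAC and by −log10 of the adjusted p-value, then height, for HA. For histone marks the longest run of windows was taken. Up to 3 accessible regions without a tall peak per HA set were added after their values were seen. The gene annotation at hand is of an earlier mouse build, so genes, promoters, gene lists and the exons of the expressed demethylases were not analysed here, nor was base composition, and no coordinates were converted. The overlap between demethylases, planned on promoter genes, was run on 1 kb windows that hold any base of a peak (Jaccard index). Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.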

Results

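E14TG2a mouse embryonic stem cells overexpressed 1 of 4 HA-tagged histone demethylases, full length or without its intrinsically disordered region (ΔIDR). KDM4A and KDM4B act on methylated H3K9, and KDM6A (UTX) and KDM6B on H3K27me3, the mark laid down by Polycomb repressive complex. Each assay, demethylase and variant had 2 libraries, 48 in all: 16 for ATAC-seq, 16 for CUT&RUN of the HA tag, 8 for CUT&RUN of H3K9me3 and 8 for CUT&Tag of H3K27me3. HA lists held 7439 to 27820 peaks per library, ATAC lists 74079 to 164442, H3K9me3 lists 38117 to 55107 and H3K27me3 lists 52234 to 161889. Errors below are SDs with n = 2 libraries. Regions are given by chromosome and GRCm39 position, and heights are the deposited HA peak heights. H3K9me3 was profiled only in cells with KDM4A or KDM4B, and H3K27me3 only in cells with KDM6A or KDM6B. Common sets and counts out of 8 libraries therefore class regions of the other demethylases by a mark measured in other cells.

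The HA comparisons asked where each tagged enzyme was found with and without its disordered region. In KDM4A, 4674 regions were gained (in both ΔIDR and neither full-length library) and 1076 were lost (the reverse), a 4.34-fold excess (log2 2.12, against an absolute 1.85 in another split of the same libraries), with 3554 shared by all 4 libraries. The patterns that mix 1 library of each variant held 274 to 1090 regions, so only the gained count exceeded them. The share of regions of either library that both held (Jaccard index) was 0.190 for full-length, 0.488 for ΔIDR and 0.223 between variants. Better agreement of the ΔIDR libraries by itself gives more gains than losses, so the excess cannot be told apart from it. In KDM4B these values were 0.209, 0.149 and 0.0930, in KDM6A 0.202, 0.261 and 0.223, and in KDM6B 0.336, 0.314 and 0.239. Of the gained regions, 59.5% lay outside the common accessible, H3K27me3 and H3K9me3 sets and 57.7% held a peak of height above 50, against 29.1% and none of the lost regions. Shared regions were mostly accessible (79.3%), and 29.2% of them overlapped common H3K27me3. The gained region of highest rank was at 82315059–82315465 on chromosome 10 (heights 548 and 552), with no ATAC peak in any of 16 libraries. Among accessible gained regions, picked after their values were seen, were 9018158–9021856 on chromosome 17 (23 and 23, with H3K27me3 in 8 of 8 libraries) and 75569658–75571252 on chromosome 11 (22 and 25). The lost region of highest rank was 4762122–4762744 on chromosome 6 (28 and 20), and an accessible one was 46043715–46044436 on chromosome 9 (18 and 16). HA peaks numbered 17982 ± 5869.7 in full-length and 19000.0 ± 198 in ΔIDR libraries, which overlapped; with −log10 q of at least 5 the log2 difference was 1.31. The share of HA peaks in H3K9me3 regions was lower in both ΔIDR libraries, 4.08% ± 0.143 against 6.27% ± 1.06. Without full-length replicate 1 the log2 ratio of gains to losses was −1.16 and without replicate 2 it was 0.0139, where a loss needs a single library, which by itself lowers the ratio. It was −0.42 when 1 library per variant sufficed, and without peaks of height above 50 the gained regions numbered 1994.

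KDM4B went the other way. Its ΔIDR libraries held 7813 ± 528 HA peaks against 16097 ± 128 in full-length libraries (0.485-fold), and covered 6.74 ± 0.936 Mb against 21.3 ± 0.0992 Mb. Regions lost numbered 3502 and regions gained 416 (log2 −3.07), both above the 222 to 287 of the mixed patterns. Most of the difference lay in accessible chromatin: 58.7% ± 2.69 of full-length peaks and 20.5% ± 1.88 of ΔIDR peaks overlapped KDM4B ATAC regions. Peaks inside those regions averaged 9454 in full-length and 1604.5 in ΔIDR libraries, while peaks outside averaged 6642.5 and 6208. Of the lost regions, 79.8% were accessible without H3K27me3, against 2.88% of the gained regions, of which 90.9% lay outside all 3 common sets. Accessible lost regions, picked after their values were seen, included 35926823–35929235 on chromosome 5 (heights 28 and 37), 100395606–100402525 on chromosome 6 (26 and 28) and 23454967–23456851 on chromosome 11 (21 and 26, with H3K9me3 in 8 of 8 libraries). The highest-ranked lost region, 58442656–58443017 on chromosome 15 (96 and 90), and the highest-ranked gained region, 76350877–76351116 on chromosome X (267 and 254), had no ATAC peak. A region at 13769073–13773640 on chromosome 17 held HA peaks in all 16 libraries (28 and 40 in full length, 43 and 43 in ΔIDR). With −log10 q of at least 5 the log2 difference in peak number was −0.24 in place of −1.04 and the lost regions numbered 397 (log2 ratio −0.43), and with equal numbers of peaks 1472 (−1.66). Without ΔIDR replicate 1 or 2 the ratio was 0.48 or 0.26, since a gain then needs a single library.

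In KDM6A, gained regions (996) and lost regions (550) did not exceed the mixed patterns (367 to 1003), and their log2 ratio of 0.86 was below the 1.45 of another split of the same libraries. HA peaks numbered 14549 ± 2432 in full-length and 14403 ± 853 in ΔIDR libraries. The share in accessible regions was higher in both ΔIDR libraries (53.8% ± 1.39 against 42.9% ± 5.45), a difference of 10.9 points that was 1.45 with −log10 q of at least 5. Of gained regions 67.9% were accessible without H3K27me3, and of lost regions 46.9%. Examples picked after their values were seen were gained regions at 87649805–87650536 on chromosome 8 (heights 11 and 12) and 121769772–121771075 on chromosome 1 (12 and 10), and a lost region at 97091376–97092084 on chromosome 6 (28 and 44). The highest-ranked gained region was 59427651–59428175 on chromosome 17 (99 and 102), and the highest-ranked lost region, 58442839–58443111 on chromosome 15 (151 and 119), overlapped that of KDM4B. The share in H3K27me3 regions was 23.8% ± 0.522 in ΔIDR and 20.5% ± 0.290 in full-length libraries, but the difference was −1.90 points when each variant was set against its own H3K27me3 regions. The log2 ratio of gains to losses moved with each library left out: it was −2.68 and −1.77 without full-length replicates 1 and 2, and 2.79 and 3.05 without ΔIDR replicates 1 and 2.

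KDM6B had the longest HA lists on average, with 26892 ± 1312 peaks in ΔIDR and 21399.5 ± 1438 in full-length libraries, and its gained (4363) and lost regions (2459) both exceeded the mixed patterns (749 to 1333). The regions differed in chromatin class: 20.7% of gained and 1.71% of lost regions were accessible with H3K27me3, while 45.6% and 78.1% were accessible without it. The share of HA peaks in KDM6B H3K27me3 regions was 20.02% ± 0.903 in ΔIDR against 10.5% ± 0.00204 in full-length libraries. Examples picked after their values were seen were gained regions at 47720038–47721125 on chromosome 6 (heights 27 and 19, with H3K27me3 in 8 of 8 libraries) and 70604940–70605929 on chromosome 8 (17 and 17, in 7 of 8). Lost ones were 137343883–137349971 on chromosome 1 (21 and 25) and 181654118–181654904 on chromosome 2 (22 and 24). They had H3K9me3 in 7 and 8 of 8 libraries, all from cells with KDM4A or KDM4B. The highest-ranked lost region was 109746381–109747012 on chromosome 5 (78 and 68), and the highest-ranked gained one was 76351019–76351044 on chromosome X (588 and 410). The log2 ratio of gains to losses was 0.83, like that of another split of these libraries (0.83). It was −0.83 and −0.57 without full-length replicates 1 and 2, 1.86 and 2.05 without ΔIDR replicates 1 and 2, and −0.39 with −log10 q of at least 5. At that threshold the H3K27me3 share differed by 1.45 points, and the log2 differences turned to −0.0944 in peak number (0.33 with all peaks) and −0.57 in covered length (0.38).

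**Figure D1:**
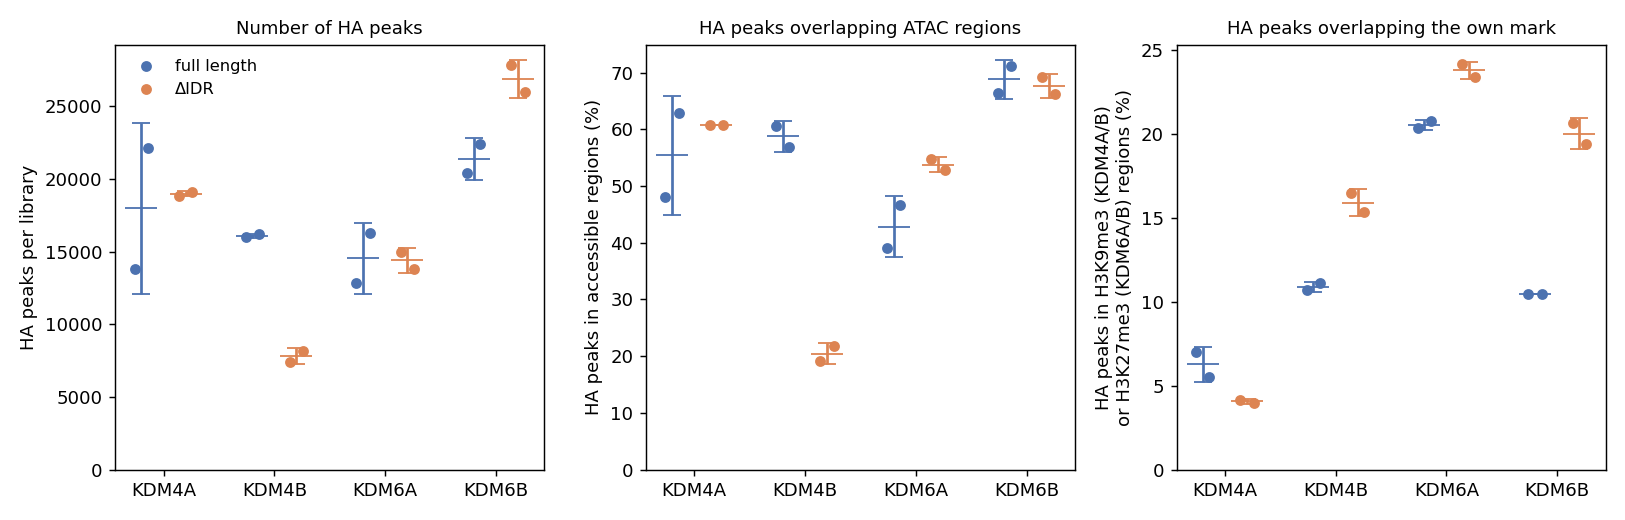
HA peaks per library (left, number), their share in accessible regions (middle, %) and in H3K9me3 or H3K27me3 regions (right, %), by demethylase, for full-length and ΔIDR libraries. Points are libraries and bars the mean and SD of 2; KDM4B ΔIDR lies lowest in number (mean 7813) and in accessible share (20.5%), and the KDM6B share in H3K27me3 is 20.02% in ΔIDR and 10.5% in full length.

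**Figure D2:**
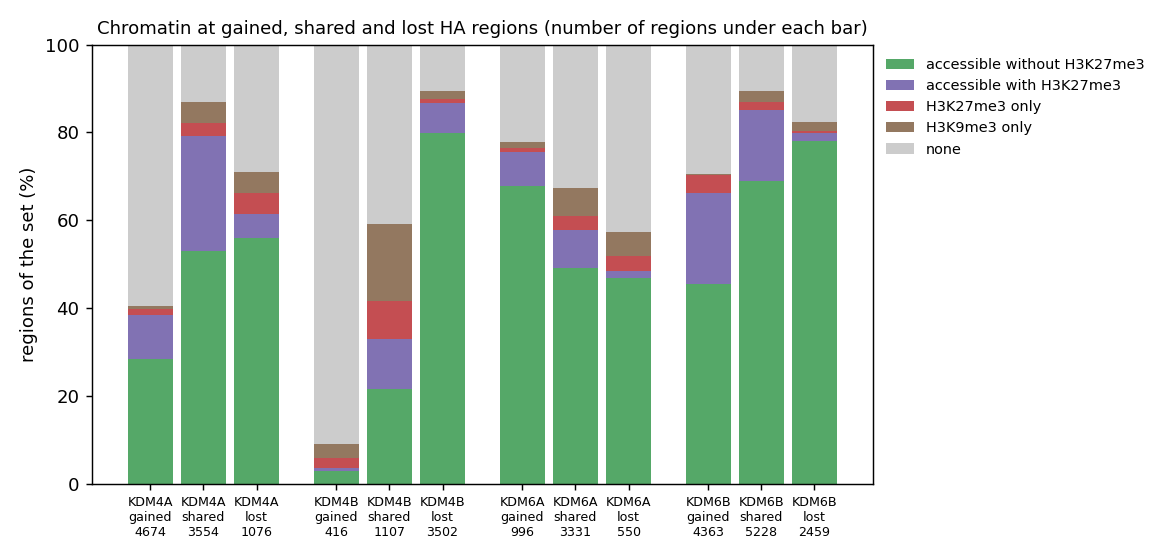
Chromatin class of gained, shared and lost HA regions of each demethylase (% of the regions of a set, whose number stands under its bar), by overlap with common accessible, H3K27me3 and H3K9me3 regions. Accessible regions without H3K27me3 make up 79.8% of the KDM4B lost regions, and 20.7% of the KDM6B gained regions are accessible with H3K27me3.

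Across the 4 demethylases, HA peak number differed by a log2 of −0.15 between ΔIDR and full length (exact p = 0.378) and covered length by −0.38 (exact p = 0.204). The share in accessible regions differed by −5.80 points (exact p = 0.313). Its effects were −38.3 in KDM4B and 10.9 in KDM6A, and, with overlapping libraries, −1.17 in KDM6B and 5.32 in KDM4A (48.0 and 62.8% in full-length, 60.8 and 60.8% in ΔIDR libraries). With −log10 q of at least 5 it differed by −18.0 points (exact p = 0.0154, adjusted 0.278, from 0.278 to 0.883 over the alternatives other than libraries left out), with −14.0 in KDM4A, −36.4 in KDM4B, 1.45 in KDM6A and −23.2 in KDM6B. Without tall peaks it differed by −0.956 points, with 18.5 in KDM4A and 2.37 in KDM6B. The share in the own mark was 3.91 points higher, in 3 of 4 demethylases (exact p = 0.0201, adjusted 0.176). It differed by 2.001 points with equal numbers of peaks, higher in 2 of 4 (exact p = 0.127), and by −0.566 with −log10 q of at least 5 (exact p = 0.656), with adjusted p from 0.185 to 0.966 over the alternatives other than libraries left out. The log2 ratio of gains to losses averaged 0.18 (exact p = 0.821). Of the 18 planned tests over all assays, 3 had an exact p under 0.05 and none passed adjustment. In tests chosen after the lists were seen, HA peaks overlapping common H3K27me3 were 3.05 points more frequent, in 3 of 4 demethylases (exact p = 0.0309, adjusted 0.123), with 17.4% against 8.63% in KDM6B and 18.4% against 15.2% in KDM4A.

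Whether the 4 enzymes occupied more similar regions without their disordered regions was asked with the Jaccard index of 1 kb windows between libraries of different demethylases. It averaged 0.166 between full-length and 0.131 between ΔIDR libraries (difference −0.0351, exact p = 0.181), and differed by −0.0424 with equal numbers over all 16 libraries (exact p = 0.0386, with adjusted p from 0.174 to 0.672 over the alternatives other than libraries left out). The pairs with KDM4B were lower in ΔIDR, such as KDM4B and KDM6B (0.0603 against 0.180), while KDM4A and KDM6B were higher (0.189 against 0.159). Without KDM4B the difference was 0.0126.

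Tall HA peaks, of height above 50, were examined after the lists were seen. They were more numerous in both ΔIDR than in both full-length libraries of every demethylase: 3714 ± 251 against 383 ± 50.9 in KDM4A, 826 ± 2.83 against 383 ± 65.1 in KDM4B, 1414 ± 37.5 against 1157 ± 158 in KDM6A and 2081 ± 219 against 585 ± 107 in KDM6B. The mean log2 difference was 1.63, in 4 of 4 demethylases (exact p = 0.00154, the smallest possible; adjusted over 8 such tests 0.0123). These peaks were narrow, with a median width of 170 to 426 bp per library, and 2.09 to 10.7% of them overlapped common accessible regions, against 14.0 to 72.9% of other peaks. Of the positions tall in both KDM4A ΔIDR libraries, 76.5% held a peak in a ΔIDR library of another demethylase, and of those of the other demethylases at least 99.4%.

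The ATAC comparisons asked whether accessibility differed with the variant expressed. In KDM6A, ATAC peaks numbered 145612 ± 2065 in ΔIDR and 101232 ± 18347 in full-length libraries (1.45-fold), with 18958 regions gained and 944 lost (mixed patterns 1566 to 4432). In KDM4B, 10322 regions were gained and 3929 lost (3599 to 4316), with 162174 ± 3208 against 147065 ± 1472 peaks. In KDM6B, 5776 were gained and 1879 lost (1615 to 4294), with 93418 ± 4425 against 82070.0 ± 11301 peaks. In KDM4A the order was the opposite, with 2656 gained and 5539 lost (2345 to 3350) and 92214 ± 1029 against 97167 ± 3202 peaks. The highest-ranked gained regions included 12165352–12165564 on chromosome 2 in KDM6A (deposited folds 49.1 and 50.2) and 102794344–102794688 on chromosome 15 in KDM6B (44.7 and 47.2). The highest-ranked lost regions included 37403998–37404175 on chromosome 5 in KDM4B (68.0 and 73.0) and 32830174–32830357 on chromosome 19 in KDM4A (41.1 and 44.3). Over demethylases the log2 difference in peak number was 0.20, higher in 3 of 4 (exact p = 0.0293, adjusted 0.176), and in the ratio of gains to losses 1.57 (exact p = 0.0525), which was 0.81 without KDM6A full-length replicate 1 and had an exact p of 0.0139 to 0.253 with 1 library left out. The lowest local background (for ATAC the most frequent recovered value), an index of depth, moved with the peak number in each demethylase: ΔIDR over full length was 0.642 in KDM4A, 1.21 in KDM4B, 1.84 in KDM6A and 1.47 in KDM6B. At equal lowest background, which stands in for depth, peak number differed by a log2 of 0.0177 in KDM4A and 0.0639 in KDM6B, with overlapping libraries in both, 0.0835 in KDM4B and 0.35 in KDM6A. Over demethylases that was 0.13, higher in 4 of 4 (exact p = 0.0170, adjusted 0.1204, from 0.1204 to 0.567 over the alternatives other than libraries left out). Thinning only removes peaks from lists with a higher background and restores none, so it can correct too far. In KDM4A this fell mostly on the full-length lists, so its small positive value, and with it the 4 of 4, is not secure. ATAC covered length at equal lowest background differed by a log2 of 0.195 (exact p = 0.0648), against 0.236 with all peaks (exact p = 0.0694), higher in 3 of 4. Thinning drops whole peaks and leaves the widths of the others, so depth can still act on covered length. The ratio of gains to losses was then 1.07 in place of 1.57 (exact p = 0.0417, adjusted 0.188). For equal numbers of peaks the KDM6A ratio was 0.46 in place of 4.33. Without KDM6B full-length replicate 1 the KDM6B ratio was −0.60, and without KDM4A ΔIDR replicate 1 or 2 the KDM4A ratio was 0.15 or 0.31.

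**Figure D3:**
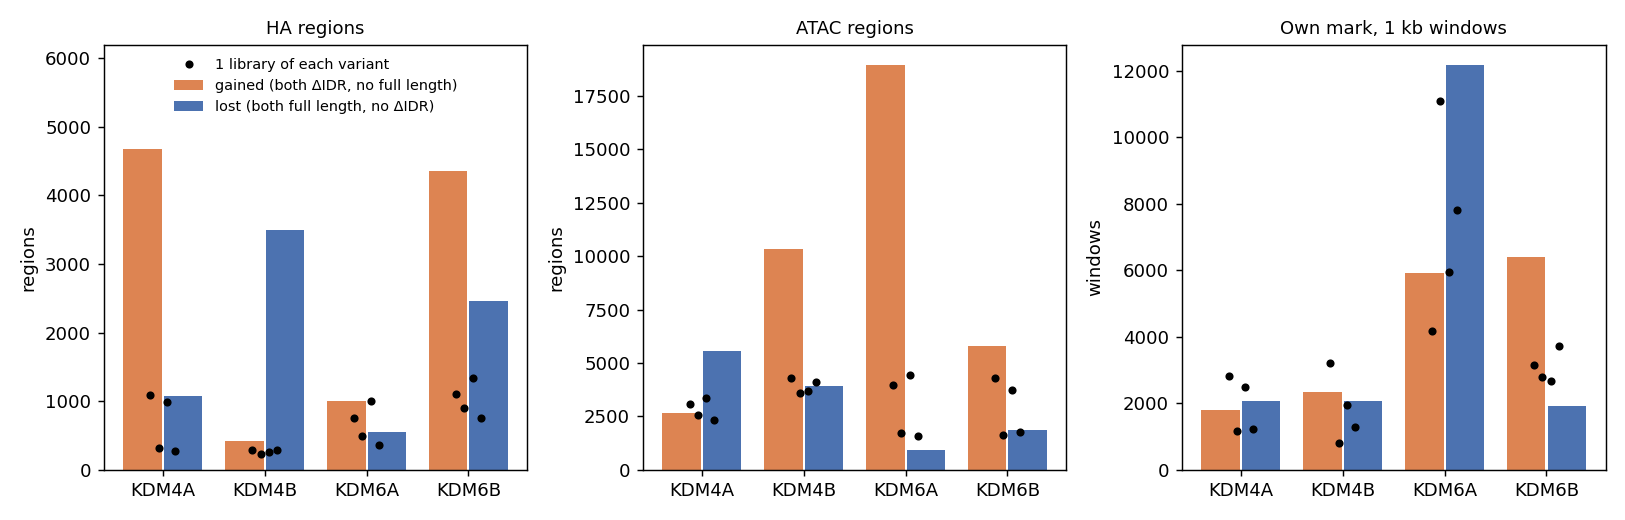
Regions gained and lost in ΔIDR against full length, by demethylase, for HA (left), ATAC (middle) and the own mark in 1 kb windows (right, H3K9me3 for KDM4A and KDM4B, H3K27me3 for KDM6A and KDM6B). Bars are counts and points the 4 patterns that mix 1 library of each variant; the KDM4B HA losses (3502) and KDM6A ATAC gains (18958) stand far above the points.

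H3K9me3, the mark on which KDM4A and KDM4B act, was compared to ask whether it differed with the variant. It covered 31.5 ± 6.20 Mb in KDM4A full-length and 31.1 ± 0.814 Mb in ΔIDR libraries, and 30.2 ± 8.65 Mb and 31.0 ± 4.26 Mb in KDM4B, with overlapping libraries in both. KDM4A had 1805 windows gained and 2069 lost (mixed patterns 1159 to 2830), and KDM4B 2325 and 2051 (787 to 3196), so neither exceeded library-to-library variation. The longest gained run in KDM4B, 7103001–7105000 on chromosome 1, had deposited folds of 3.11 and 2.97 in ΔIDR and no peak in full-length libraries. The longest lost run in KDM4B and the longest gained and lost runs in KDM4A held peaks in both variants. The H3K9me3 covered length differed by a log2 of 0.0267 over both demethylases (exact p = 0.944, smallest possible 0.0556).

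H3K27me3 was compared in the same way for KDM6A and KDM6B. Called H3K27me3 peaks covered more in KDM6B ΔIDR than in full-length libraries, 62.4 ± 5.37 Mb against 49.0 ± 2.38 Mb (1.27-fold), with 6392 windows gained and 1907 lost (mixed patterns 2654 to 3712). The median fold of these peaks was 2.92 and 2.98 in ΔIDR and 3.02 and 2.95 in full-length libraries. Histone lists have no index of depth here, so longer lists cannot be told apart from deeper libraries. KDM6A ΔIDR libraries had fewer H3K27me3 peaks, 127200.0 ± 10383 against 152799 ± 12855, and covered 138 ± 12.7 Mb against 157 ± 19.8 Mb, which overlapped. There, 12175 windows were lost and 5923 gained (4162 to 11081), a log2 ratio of −1.04, within the absolute 1.41 of another split of the same libraries, while that of KDM6B was 1.74 against 0.48. The longest lost run in KDM6B, 104149001–104152000 on chromosome 2, had deposited folds of 2.99 and 2.79 in full-length and no peak in ΔIDR libraries. The longest gained run, 14733001–14737000 on chromosome 8, held peaks in both variants, with folds of 2.86 and 2.88 in full-length and 2.58 and 2.99 in ΔIDR libraries. The longest gained and lost runs in KDM6A also held peaks in both variants. Such runs differ in how much of a window peaks covered, not in the presence of peaks. Over both demethylases, covered length differed by a log2 of 0.0798 (exact p = 0.611). With −log10 q of at least 5 the log2 ratios were larger, −4.64 in KDM6A (235 windows gained and 5896 lost) and 5.40 in KDM6B (1305 and 30), with covered length at a log2 of −1.04 and 1.22. With equal numbers of peaks the log2 ratio was 0.45 in place of −1.04 in KDM6A and 0.33 in place of 1.74 in KDM6B. In KDM6B it was 0.0376 and −0.11 without full-length replicates 1 and 2, and in KDM6A 0.42 without ΔIDR replicate 2.

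Own-mark coverage was measured at the HA regions themselves. In KDM6A, H3K27me3 covered 11.1% ± 1.21 of gained HA regions in ΔIDR and 15.5% ± 2.64 in full-length libraries, and 5.58% ± 0.292 against 8.34% ± 1.54 of lost regions. In KDM6B it covered 15.1% ± 1.49 of gained regions in ΔIDR and 12.9% ± 0.301 in full-length libraries, following the genome-wide order of each demethylase. With equal numbers of peaks the difference at KDM6B gained regions turned from 2.22 to −1.13 points. H3K9me3 covered 0.436% ± 0.0251 and 0.404% ± 0.0898 of the KDM4A gained regions and 4.62% ± 0.628 and 4.31% ± 0.305 of those of KDM4B. Over demethylases the difference was −0.456 points at gained (exact p = 0.664), −0.466 at lost (exact p = 0.397) and −0.0426 at shared regions (exact p = 0.931). At equal numbers of peaks it was −1.31 at gained regions, lower in 4 of 4 (exact p = 0.0185, adjusted 0.167, from 0.167 to 0.966 over the alternatives other than libraries left out). Without KDM6A full-length replicate 1 of H3K27me3 the value at gained regions was 0.0109. At lost regions it was −0.738 without full-length replicate 2 of H3K27me3 in KDM6A and −0.112 without full-length replicate 2 of HA in KDM6A, where the KDM6A difference was −3.85 and −1.34 in place of −2.76.

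Accessibility was measured in the same way, as the share of HA regions with an ATAC peak. The largest difference was in KDM6A, with 53.4% ± 0.129 of lost regions in ΔIDR and 48.5% ± 1.16 in full-length libraries, and 63.0% ± 0.382 against 59.8% ± 0.913 of shared regions. Of the regions that KDM4B lost, 90.9% ± 0.0808 had an ATAC peak in full-length and 90.9% ± 0.242 in ΔIDR libraries; in the deposited names the KDM4B ΔIDR ATAC libraries carry a different tag from the HA and H3K9me3 libraries. KDM6A had an ATAC peak at 77.9% ± 0.0710 of gained regions in ΔIDR and 75.6% ± 1.63 in full-length libraries, and KDM6B at 67.7% ± 0.0810 and 64.9% ± 1.59. In KDM4A it was 38.5% ± 0.0454 and 39.2%, the latter the same in both full-length libraries. Over demethylases the difference at gained regions was 1.40 points, higher in 3 of 4 (exact p = 0.0185, adjusted 0.176), at lost regions 1.45 (exact p = 0.137) and at shared regions 1.02 (exact p = 0.0787). At equal lowest ATAC background they were 1.14 (exact p = 0.0170), 0.801, higher in 2 of 4 (exact p = 0.227), and 0.582 (exact p = 0.151). Without full-length ATAC replicate 1 the KDM6A difference at gained regions was 1.15 in place of 2.31, and that of KDM6B was 1.68 in place of 2.81 at gained, 0.773 in place of 2.62 at lost and 0.488 at shared regions. The values over demethylases at equal numbers of peaks were 0.211 (exact p = 0.443), −0.503, lower in 4 of 4 (exact p = 0.0154, adjusted 0.167, from 0.167 to 0.966 over the alternatives other than libraries left out), and −0.386 (exact p = 0.0864).

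Chromosomes 6 and 8 stood apart in the HA lists. Chromosome 8 held 10.0 to 21.2% of HA peaks per library and 5.74 to 6.17% of ATAC peaks, and chromosome 6 held 6.76 to 20.1% and 5.64 to 6.81%. Of KDM4A lost regions 24.0% lay on chromosome 8, against 3.68% of gained ones. Chromosome 6 held 20.4% of lost and 4.57% of gained regions in KDM4B, and 17.3% and 5.32% in KDM6A. At ATAC regions shared by all 4 libraries, the recovered pileup on chromosome 6 relative to other autosomes differed between ΔIDR and full length by a log2 of −0.22 in KDM4A, −0.24 in KDM4B, −0.0879 in KDM6A and −0.0473 in KDM6B. On chromosome 8 it differed by 0.00182, −0.0299, 0.0244 and 0.0770, and the 17 autosomes other than 6 and 8 lay between −0.0277 and 0.0495. In KDM6B chromosome 8 thus went the other way, with 10.7% of gained and 5.65% of lost HA regions, and its relative HA height differed by 0.133, where other autosomes lay between −0.185 and 0.134. Without both chromosomes KDM4B had 2270 lost HA regions.

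**Figure D4:**
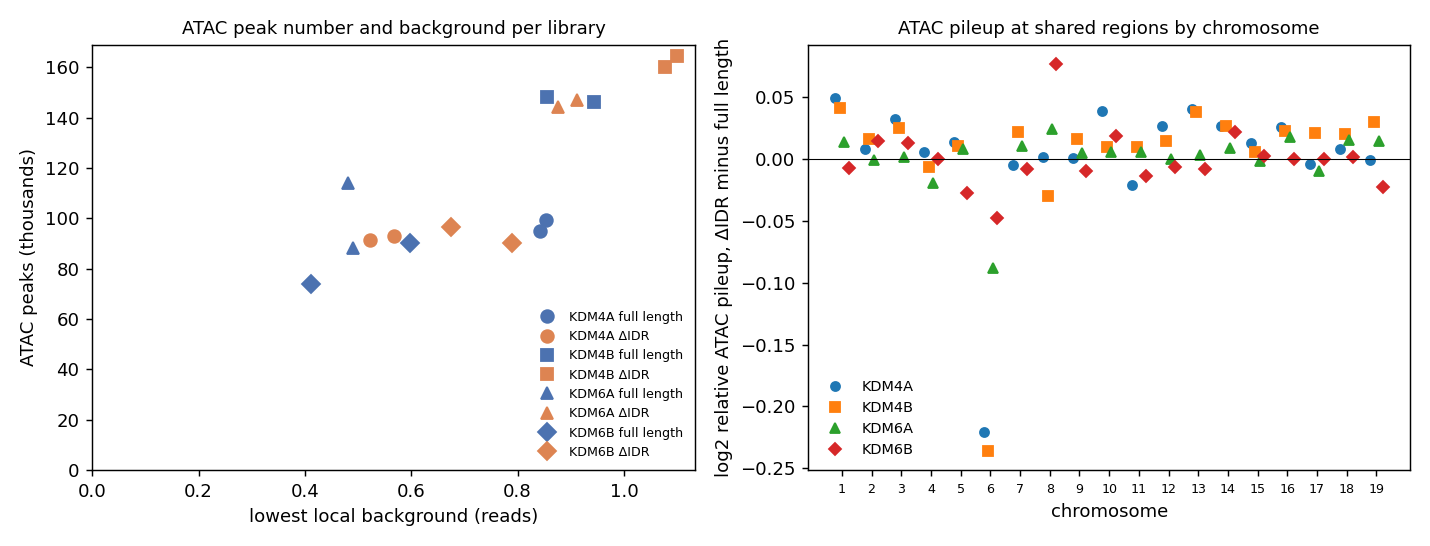
Left, ATAC peaks per library (in units of 1000 peaks) against the lowest local background (reads, the most frequent recovered value), by demethylase and variant. Right, log2 of the relative ATAC pileup at regions shared by all 4 libraries, ΔIDR minus full length, for each autosome and demethylase; chromosome 6 is lowest, at −0.24 in KDM4B and −0.22 in KDM4A.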

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

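The tests of chromosome copies and of failed enrichment below were set up before their values were seen; those of accessibility and read number in KDM4B, all tests of tall peaks and the setting of chromosome 6 against other autosomes were chosen after the result was seen.

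HA regions lost in ΔIDR libraries lay more often on chromosome 8 (KDM4A) or chromosome 6 (KDM4B, KDM6A) than gained regions. For KDM4A, more copies of chromosome 8 in the full-length culture used for ATAC is argued against, since relative ATAC pileup there differed by a log2 of 0.00182; the relative HA height differed by −0.0928, between the bounds set in advance, so the HA cultures stay open. For KDM4B, more copies of chromosome 6 are a candidate explanation in the full-length culture used for ATAC alone. Relative pileup at shared ATAC regions differed by −0.24 (log2, ΔIDR minus full length), with −0.25 to −0.21 in 6 bins of 25 Mb, and by −0.00623 to 0.0416 on the 17 autosomes other than 6 and 8. In the KDM4B HA libraries copies cannot be told apart from library noise: relative height on chromosome 6 differed by −0.292, past the bound set in advance, but by −0.291 on chromosome 7 and −0.321 on chromosome 13, where ATAC differed by 0.0220 and 0.0380. The ATAC value cannot stand in for the HA cultures, since the KDM4B ΔIDR ATAC libraries carry a different tag in the deposited names, and in KDM4A an ATAC shift of −0.22 on chromosome 6 went with an HA height of 0.0689. For KDM6A the relative ATAC pileup on chromosome 6 differed by −0.0879, with libraries apart, −0.117 to −0.0548 in the 6 bins and −0.0194 to 0.0179 on the other 17 autosomes, which is more than their spread. It falls between the bounds set in advance, so copies in part of the cells cannot be told apart from another difference along the whole chromosome. The relative HA height there differed by −0.0670 with overlapping libraries, also between the bounds, and decides nothing. No biological explanation was tested, and without chromosomes 6 and 8 the KDM4B log2 ratio of gains to losses was −2.68 in place of −3.07.

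KDM4B ΔIDR lists lacked most of the accessible regions of the full-length lists. Loss of accessibility there, as the whole cause, is argued against by a share of lost regions with an ATAC peak that differed by 0.0285 points. A partial fall large enough to be the whole cause, which that share could miss, is argued against by ATAC fold at 3685 ATAC regions overlapping them and called in all 4 libraries, which 88.98% of the lost regions had: against regions of like fold on the same chromosome it differed by −0.0404 (log2), and against all other shared ATAC regions by −0.0825, where a fall of 0.3 was set as needed and one under 0.1 as too small. Those regions leave out sites that dropped below the call limit. Over all 4242 overlapping ATAC regions of any library, with the lowest fold of the list where a library had no peak, it differed by −0.0466 (median) and −0.0684 (mean), and 64 were called in both full-length libraries alone against 37 in both ΔIDR libraries alone. These tests have the limit that the ΔIDR ATAC libraries carry a different tag in the deposited names. Fewer reads in the ΔIDR HA libraries can be neither excluded nor shown. The ratio of lowest backgrounds was 0.984, with overlapping libraries, but whether the lowest HA background tracks read number is not known. The number of peaks changed by a log2 of −2.57 inside accessible regions and −0.0964 outside them, which describes the pattern and is no separate test. Failed HA enrichment cannot be told apart from less binding by the ΔIDR protein, since heights at 461 accessible regions shared by all 4 libraries differed by −0.32 (log2), which either would give, and no library lacks the tag. An effect of the deleted region on binding, or a lower level of the ΔIDR protein, may contribute and was not tested.

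Tall HA peaks were more numerous in ΔIDR than in full-length libraries of all 4 demethylases. Binding to accessible chromatin is argued against, since the share of tall peaks in common accessible regions was at most 0.327 times that of other peaks in any of the 16 libraries. More reads in the ΔIDR libraries can be neither excluded nor shown, since whether the lowest HA background tracks read number is not known. In KDM4B the ratio of lowest backgrounds was 0.984 and tall peaks were 2.17-fold more numerous. The lowest background was higher in ΔIDR in the others, 1.22-fold in KDM4A, 1.101 in KDM6A and 1.097 in KDM6B. With heights scaled to equal lowest background tall peaks were still 9.19-fold (9.73 unscaled) more numerous in KDM4A and 3.51-fold (3.58) in KDM6B. In KDM6A, at 1.17-fold (1.23), read number could not be told apart from another cause even if the lowest background tracked it. Positions that gather reads whichever demethylase is tagged cannot be told apart from binding by the ΔIDR proteins. On average 94.0% of the positions tall in both ΔIDR libraries held a peak in a ΔIDR library of another demethylase. Full-length libraries of other demethylases held a peak at 55.1% of them in KDM4A, 92.3% in KDM4B, 76.6% in KDM6A and 76.3% in KDM6B. The full-length libraries of the same demethylase, which are fewer, held a peak at 19.7% in KDM4A, 63.8% in KDM4B, 92.4% in KDM6A and 46.8% in KDM6B. Why they were more numerous in ΔIDR libraries was not tested, and no library without a tagged protein is among the samples.

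Between demethylases, several effects of ΔIDR against full length had opposite signs, with all libraries of each apart; none of these differences between demethylases was itself tested. HA peak number differed by a log2 of 0.33 in KDM6B and −1.04 in KDM4B, and HA covered length by 0.38 and −1.67. ATAC peak number differed by 0.54 in KDM6A and −0.0751 in KDM4A, and ATAC covered length by 0.60 and −0.32. The number of H3K27me3 peaks differed by 0.29 in KDM6B and −0.26 in KDM6A. The share of HA peaks in accessible regions differed by 10.9 points in KDM6A and −38.3 in KDM4B, and the share in the own mark by 9.56 in KDM6B and −2.20 in KDM4A. H3K27me3 coverage differed between KDM6B and KDM6A by 2.22 and −4.40 points at gained HA regions, 0.201 and −2.76 at lost regions, and 0.983 and −1.76 at shared regions. The share of HA regions with an ATAC peak differed by 2.81 points in KDM6B and −0.717 in KDM4A at gained regions; at lost regions by 4.91 in KDM6A and −1.77 in KDM4A, and at shared regions by 3.17 and −1.01.

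Outside the main chromosomes, a sequence named dm, which the labels do not describe, held 1917 to 4049 peaks per ATAC library and 3 to 38 per H3K9me3 library, and none in HA or H3K27me3 libraries. Among the reported comparisons, dm peaks entered only the alternative with all sequences.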

How the results depend on the processing

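Alternatives without tall HA peaks, at equal lowest ATAC background, without chromosomes 6 and 8 and without KDM4B were chosen after the data were seen; the others were planned. None of the 18 tests over demethylases passed adjustment with the lists as deposited, and none did under any alternative run. Apart from libraries left out, 102 of 113 values over demethylases kept their direction and 11 did not. The 102 include the 18 with replicate number as a block, which could not change direction. With 1 library left out, 395 of 416 kept it and 21 did not. Unknown depth, 2 libraries per group and called peaks in place of reads limit all comparisons. Where a value below changed, the cause was not tested unless a cause is given.

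With −log10 q of at least 5, HA peak number differed by a log2 of 0.27 over demethylases, in place of −0.15, by 1.31 in KDM4A, −0.24 in KDM4B and −0.0944 in KDM6B, and HA covered length by −0.57 in KDM6B. ATAC peak number differed by −0.19 in KDM4A and 0.0602 in KDM4B. Covered length of H3K9me3 differed by −0.28 in KDM4B, and of H3K27me3 by −1.04 in KDM6A and 1.22 in KDM6B. The HA share in accessible regions differed by −14.0 points in KDM4A, 1.45 in KDM6A and −23.2 in KDM6B. The share in the own mark differed by −0.566 over demethylases, −4.79 in KDM4A, 1.38 in KDM4B, −0.308 in KDM6A and 1.45 in KDM6B. Own-mark coverage at shared HA regions differed by 0.0310 over demethylases, and accessibility at those of KDM4B by −0.310. Log2 ratios of gains to losses were −0.43 for KDM4B and −0.39 for KDM6B (HA), −2.08 for KDM4A and 0.85 for KDM4B (ATAC), and −4.64 for KDM6A and 5.40 for KDM6B (H3K27me3).

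With equal numbers of peaks, the accessible share differed by −46.1 points in KDM4B and the own-mark share by −0.208 in KDM4B and 7.36 in KDM6B. Own-mark coverage differed by −1.13 at KDM6B gained, −0.0430 at KDM4B lost and −0.0904 at KDM6B shared regions. Accessibility differed by −0.503 at lost regions over demethylases (−0.934 in KDM6A, −0.184 in KDM6B) and by −0.386 at shared regions (−1.08 in KDM4B, −0.0465 in KDM6B). Log2 ratios were −1.66 for KDM4B and 0.0610 for KDM6B (HA), −0.57 for KDM4A, 0.39 for KDM4B, 0.46 for KDM6A and 0.33 for KDM6B (ATAC), and 0.45 for KDM6A and 0.33 for KDM6B (H3K27me3).

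With the other overlap rule (50% of a region, or any base of a window), log2 ratios were −0.20 over demethylases and −3.49 for KDM4B (HA), and −1.79 for KDM4A and 1.84 for KDM4B (ATAC); own-mark coverage at shared regions differed by 0.163. Where 1 library sufficed for a gain or loss, ratios were −0.29 over demethylases, −0.42 for KDM4A and −1.22 for KDM4B (HA), −0.30 for KDM4A, 0.88 for KDM4B and 2.13 for KDM6A (ATAC), and 0.74 for KDM6B (H3K27me3). Against the same variant's set, the own-mark share differed by −1.90 in KDM6A. With all sequences, and with equal numbers over all 16 HA libraries, no direction over demethylases changed.

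Without tall HA peaks, HA peak number differed by −1.17 in KDM4B, the accessible share by 18.5 points in KDM4A and 2.37 in KDM6B, and the own-mark share by 6.16 in KDM4B, 3.95 in KDM6A and 10.7 in KDM6B; HA log2 ratios were −0.56 over demethylases and −4.37 for KDM4B. At equal lowest ATAC background, peak number differed by 0.0177 in KDM4A, 0.0835 in KDM4B, 0.35 in KDM6A and 0.0639 in KDM6B (0.19 as deposited, with overlapping libraries after thinning), and log2 ratios were −0.39 for KDM4A and 0.99 for KDM4B. Without chromosomes 6 and 8, KDM4B differed by −0.88 in HA peak number and −44.4 points in accessible share, with an HA ratio of −2.68, and own-mark coverage at shared regions differed by 0.00187 over demethylases. Without KDM4B, the overlap between demethylases differed by 0.0126 in place of −0.0351.

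Leaving out 1 library moved the ratios of gains to losses by construction: with 1 library of a variant left, presence in that library is enough, so most ratios were lower without a full-length and higher without a ΔIDR library. HA ratios spanned −0.70 to 1.07 over demethylases, −1.16 to 2.58 in KDM4A, −4.55 to 0.48 in KDM4B, −2.68 to 3.05 in KDM6A and −0.83 to 2.05 in KDM6B. ATAC ratios spanned 0.81 to 1.91 over demethylases, −1.80 to 0.31 in KDM4A, 0.22 to 1.91 in KDM4B, 1.28 to 4.27 in KDM6A and −0.60 to 2.29 in KDM6B. Own-mark ratios spanned −0.29 to 0.54 over demethylases, −1.63 to 0.82 in KDM4A, −1.64 to 1.45 in KDM4B, −2.03 to 0.42 in KDM6A and −0.11 to 2.62 in KDM6B. Over demethylases, own-mark peak number spanned −0.00121 to 0.11 and covered length −0.0208 to 0.13, own-mark coverage −0.923 to 0.0109 points at gained, −0.738 to −0.112 at lost and −0.287 to 0.202 at shared regions. Accessibility spanned 1.11 to 1.88 points at gained, 0.986 to 1.91 at lost and 0.855 to 1.18 at shared regions. The own-mark share spanned 2.69 to 3.60 points in KDM6A and 8.44 to 10.2 in KDM6B.

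Counts of gained and lost regions also moved. With −log10 q of at least 5 the HA regions lost numbered 263 in KDM4A (1076 with all peaks), 397 in KDM4B (3502) and 164 in KDM6A (550), and those gained 245 in KDM6A (996) and 1293 in KDM6B (4363). ATAC regions gained numbered 1313 in KDM4A (2656) and 6184 in KDM4B (10322), and those lost 433 in KDM6A (944) and 1239 in KDM6B (1879). H3K9me3 windows gained and lost numbered 30 (1805) and 17 (2069) in KDM4A and 34 (2325) and 64 (2051) in KDM4B, and H3K27me3 windows 235 (5923) and 5896 (12175) in KDM6A and 1305 (6392) and 30 (1907) in KDM6B. With equal numbers of peaks, HA regions lost in KDM4B numbered 1472, and ATAC regions in KDM6A 5327 gained (18958) and 3870 lost (944), in KDM6B 3398 gained (5776); H3K27me3 windows were 10677 gained (5923) and 7789 lost (12175) in KDM6A, and 3760 gained (6392) and 2992 lost (1907) in KDM6B. The other overlap rule moved 11 counts: HA regions gained in KDM4B to 256 (416), ATAC regions lost in KDM4A to 9747 (5539) and gained in KDM4B to 15744 (10322) and in KDM6B to 9305 (5776). H3K9me3 windows gained and lost moved to 3988 and 4260 in KDM4A and 6458 and 4599 in KDM4B, and H3K27me3 windows to 26113 lost in KDM6A and 14676 gained and 4343 lost in KDM6B. Where 1 library sufficed all 24 counts were above 1.5 times, from 9645 HA regions gained in KDM4B (416) to 64458 ATAC regions gained in KDM6A (18958). Without tall peaks HA gains were 1994 in KDM4A (4674) and 168 in KDM4B (416), at equal lowest background ATAC losses in KDM6A were 1623 (944), and without chromosomes 6 and 8 HA losses in KDM4B were 2270.

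With 1 library left out, 86 of 96 counts were more than 1.5 times the main count and none was below it, again because fewer libraries need to share or lack a region. HA regions gained and lost spanned 5299 to 9456 and 1543 to 11833 in KDM4A, 565 to 5366 and 3859 to 13297 in KDM4B, 1389 to 7824 and 947 to 8881 in KDM6A, and 5417 to 15496 and 3731 to 9624 in KDM6B. ATAC regions spanned 5172 to 13109 and 10578 to 18031 in KDM4A, 18116 to 31449 and 8389 to 15534 in KDM4B, 24802 to 43699 and 2269 to 10183 in KDM6A, and 8765 to 22575 and 4409 to 13305 in KDM6B. H3K9me3 windows spanned 3096 to 7204 and 4074 to 9599 in KDM4A, and 3648 to 9301 and 3392 to 11403 in KDM4B. H3K27me3 windows spanned 10330 to 28791 and 21543 to 42231 in KDM6A, and 10681 to 22200 and 3598 to 11527 in KDM6B.

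Replicate numbers did not pair libraries across variants: correlations between the same numbers, net of the variant, were −0.0139 to 0.00891 over 12 comparisons. With replicate number as a block (256 arrangements), the 18 values stay as they are by construction (such as 0.199 for ATAC peak number), the lowest exact p was 0.0469 and the lowest adjusted p 0.375. Not run, for want of an annotation and sequence of the same build, were a wider promoter window and the 200 bp around summits.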

Other observations

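All counts in this part were chosen after the lists were seen, and none has a test.

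Some regions held HA peaks in all libraries, which occupancy and positions that gather reads whatever is tagged would both give. Of 109266 HA regions merged over all libraries, 668 held a peak in all 16, 1592 in all 8 full-length and 1138 in all 8 ΔIDR libraries. Of the 668, 44.6% overlapped common accessible regions, 28.6% common H3K27me3 and 36.5% common H3K9me3 regions, and 15.3% lay on chromosome 8. Without tall peaks, 435 regions held a peak in all 16 libraries, of which 56.1% were accessible and 43.7% overlapped H3K9me3.

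Overlaps of gained and lost regions differed by pair of demethylases. Summed over the 6 pairs of demethylases, 1423 regions were gained in both, against 302 if gains were independent over the merged regions (4.72-fold). Of these, 870 were of KDM4A and KDM6B, against 184 if independent. Without tall peaks the sum was 278 against 118 (2.35-fold, and 0.939 to 2.77-fold by pair), with 178 against 64.2 for KDM4A and KDM6B and 3 against 3.00 for KDM4A and KDM4B. Regions lost in both numbered 611 against 166 (3.69-fold), with 227 against 33.1 for KDM4A and KDM4B, and 625 against 171 without tall peaks (3.65-fold). Regions gained in one and lost in the other numbered 632 against 549.99 (1.15-fold, and 0.386 to 3.76-fold over 12 pairings) with all peaks and 567 against 347 (1.63-fold, and 0.762 to 5.25-fold) without tall peaks. In pairs with KDM6A and without tall peaks, opposite overlap could exceed that of gains. Regions lost in KDM4B and gained in KDM6A were 4.09-fold, against 1.504-fold for gained in both (2 regions against 1.33) and 4.76-fold for lost in both (78 against 16.4). Regions gained in KDM6A and lost in KDM6B were 2.78-fold, against 2.14-fold for gained in both and 2.47-fold for lost in both.

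The X chromosome held 0.337 to 2.14% of HA peaks and 2.03 to 2.19% of ATAC peaks per library. Its HA share was higher in both ΔIDR than in both full-length libraries of KDM4A (2.06% ± 0.116 against 0.390% ± 0.0524, SD, n = 2), KDM4B (1.02% ± 0.169 against 0.360% ± 0.0323) and KDM6A (1.03% ± 0.100 against 0.736% ± 0.0502), and overlapped in KDM6B (0.676% ± 0.106 against 0.848% ± 0.138).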
